A study of Mus musculus with 6 samples.

How the data were processed

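Nuclei were isolated from the hippocampi of J20/apoE4-KI mice, stained with the DNA dye DAPI, sorted for DAPI-positive single nuclei and profiled with 10x droplet single-nucleus RNA sequencing, per the labels' protocols. The 6 samples fall into 2 groups of 3 mice: bumetanide, given daily by intraperitoneal injection at 0.2 mg/kg for 12 weeks, and vehicle. The labels give an age of 10 months for all 6 mice. Their protocols say that the samples were harvested and run together in randomised order, and name no batch.

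The deposited values are UMI counts, that is whole-number counts of distinct RNA molecules per gene and nucleus, with no normalization. Per the submitters' processing notes, Cell Ranger and the mouse build mm10 were used; the version, the annotation and whether intronic reads were counted are not given in the sources used here. The authors' deposited count matrix joins the whole series, with 32285 genes, 47619 nuclei and 60823302 UMIs. Its barcodes carry 6 suffixes, treated here as 6 barcode libraries and numbered as the suffixes are. Nothing in the sources used here says which suffix belongs to which mouse or treatment. No library was assigned to a group from its order or from its values, so bumetanide and vehicle were not compared, and the planned edgeR and DESeq2 fits were not run.

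Without that map the matrix counts as 1 pooled sample. The libraries were used to give a range and a median, to ask whether a difference between cell classes held in each of them, and to look for values of 1 library that lie apart from the others. For the last, 30 values were held against the critical value of Dixon's ratio, and genes were compared between libraries within a class. No p-value or SD was computed over libraries or nuclei. CPM means UMIs of a gene per 1000000 UMIs of the class. Intervals are 95% and exact (Poisson for CPM, conditional binomial for ratios of CPM, Clopper-Pearson for shares), and they cover counting error only. The floor of a class is the CPM that 3 UMIs would give.

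Nuclei were kept with at least 500 detected genes, at most 5% mitochondrial UMIs and no doublet call, which left 31176, or 65.5% of the matrix. The gene minimum took out 13917 nuclei, the doublet call 2817 and the mitochondrial limit 38, with some removed by more than 1 of them. Doublets were called per library with the Scrublet method in scanpy 1.11.5. In library 4 its own score threshold of 0.593 marked only 0.014% of nuclei, so the median threshold of the other libraries, 0.205, was used there and marked 6.50%. The other libraries had 4.29 to 7.09% marked.

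Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes were chosen without any gene of the fixed lists and without mitochondrial, ribosomal and sex-linked genes. Clusters came from 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, Python 3.11.15; figures with matplotlib 3.10.9). They were named from 147 markers in 23 lists, so that each class name means nuclei that resemble that type by these markers; the suffix "-like" is left out. A cluster took the list with the highest mean log2 fold over the median cluster, computed with 10 CPM added, where at least 3 markers with 5 or more UMIs were raised at least 2-fold. It stayed unnamed if it held under 20 nuclei, had a high median doublet score, or had a list of another broad class, itself with at least 3 raised markers, within 1.0 of the best mean log2 fold. These naming thresholds, and the threshold for library 4, were chosen after the clusters had been seen; an alternative that names every cluster is among the settings tried.

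The filters, the markers, 10 gene lists with 197 distinct genes, the pair of class sets each list is compared in, the calling rule and the rule for naming genes were fixed before the data were examined. One list gene, Clec7a, is not analysed here. A list gene was called higher in a class set when its pooled CPM was at least 2-fold higher there, was higher in each of the 6 libraries, and rested on at least 20 UMIs. For each list the text may name up to 10 genes called on each side, largest fold first, and up to 5 uncalled genes above 50 CPM, highest first; Slc12a2, Slc12a5, App, Apoe, Calb1 and Fos are given in any case. Values of further classes that are set beside these genes were picked after they were seen, as was the look at where the microglia of the 200-gene setting lie in the main set. Gene positions are 1-based, on mm10, from GENCODE release M21, in which all 343 list and marker genes looked up were found by Ensembl ID.

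The calling rule was tested on simulated counts drawn from these classes and libraries, with 200 genes changed. At a true fold of 3 it called 99.0% of 100 changed genes for neurons against glia, and 100% each for inhibitory against excitatory and for granule against CA1 and CA3 neurons. The share was 50.0% for astrocytes and 75.0% for mature oligodendrocytes against all other classes. At a true fold of 6 these shares were 82.0% and 99.0%. Among unchanged genes 2.58% were called lower in astrocytes and 1.02% lower in mature oligodendrocytes. The simulation gave each gene the same level in every library, added counting error only and left out rare genes. These shares therefore do not cover differences between libraries, free RNA or rare genes.

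Alternatives tried were a minimum of 200 or 1000 genes, a mitochondrial limit of 1%, no doublet removal, resolutions of 0.5 and 2.0, list genes kept in the clustering, thinning to 1000 UMIs per nucleus, medians over libraries, leaving out each library, UMIs per nucleus in place of CPM, folds of 1.5 and 3 in the rule, and no UMI minimum. Thinning kept 26717 nuclei and left out 4459 that held fewer UMIs. The median was 971.5 UMIs in astrocytes, 938 in mature oligodendrocytes and 831 in oligodendrocyte precursors, so thinning took out a large part of these classes. UMIs per nucleus shift all genes alike, by 0.68 on the log2 scale toward neurons against glia, by 0.63 toward CA1 and CA3 against granule neurons, and by 0.05 toward inhibitory against excitatory neurons.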

Results

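Single-nucleus RNA profiles were made from the hippocampus of J20/apoE4-KI mice after 12 weeks of bumetanide or vehicle, with 3 mice per group. The J20 line carries a human APP transgene with familial Alzheimer mutations. In the apoE4-KI line the human APOE4 allele, the main common genetic risk factor for late-onset Alzheimer's disease, replaces mouse Apoe. Bumetanide is a loop diuretic that blocks the sodium-potassium-chloride cotransporters encoded by Slc12a1 and Slc12a2. The series title names the purpose as repurposing the drug for Alzheimer's disease.

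The matrix held 8247, 8508, 8299, 7324, 7516 and 7725 nuclei in libraries 1 to 6. Total UMIs per library ran from 9083641 to 10883337, and the median nucleus held between 1154.5 and 1221 UMIs. After filtering, 4580 to 5737 nuclei per library remained. How bumetanide changed these nuclei, the question of the design, is not analysed here, because the libraries could not be assigned to the treatments. The comparisons below are between cell classes over all 6 mice together, and each value comes from 1 pooled sample with no replicate error.

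Dentate granule neurons, the principal cells of the dentate gyrus, made up 42.5% of the kept nuclei (95% interval 42.0 to 43.1) and 39.1 to 48.8% in single libraries. Subicular or cortical excitatory neurons followed with 19.1%, CA1 pyramidal neurons with 15.8%, inhibitory neurons with 8.44% and CA3 pyramidal neurons with 4.69%. Oligodendrocyte precursors gave 2.40%, mature oligodendrocytes 1.36%, astrocytes 0.654% and differentiating oligodendrocytes 0.180%. Choroid plexus epithelium, which makes cerebrospinal fluid, gave 1.06% and ranged from 0.296 to 2.42% over libraries. Vascular leptomeningeal cells, the fibroblasts of the brain's coverings, gave 1.06%, and 2.81% of nuclei stayed unnamed.

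Neuronal classes together made up 90.5% of nuclei (90.2 to 90.8), between 88.1 and 92.2% in single libraries. A cluster of 414 nuclei with raised markers of 2 neuronal classes stayed unnamed and is not counted in this share. This share rests on the minimum of 500 genes, as it was 69.3% with 200 genes. CA1 then stood at 9.83% and CA3 at 1.66%, with 741 CA3 nuclei in place of 1461, so that nuclei also changed class between the settings. At 200 genes mature oligodendrocytes rose to 19.2% and astrocytes to 1.22%, and microglia, the resident immune cells of the brain, formed a class of their own with 3.01%. Of the mature oligodendrocytes named at 200 genes, 95.2% were absent from the main set, against 70.7% of microglia, 62.9% of astrocytes and 9.67% of granule neurons. Neuronal RNA was present in glial nuclei: Slc17a7, the vesicular glutamate transporter of excitatory neurons, stood at 21.6% of its excitatory level in glia, at 22.7% in astrocytes and at 34.3% in mature oligodendrocytes. In the other direction Mbp, which encodes a myelin protein, stood in neurons at 1.34% of its oligodendrocyte level.

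**Figure D1:**
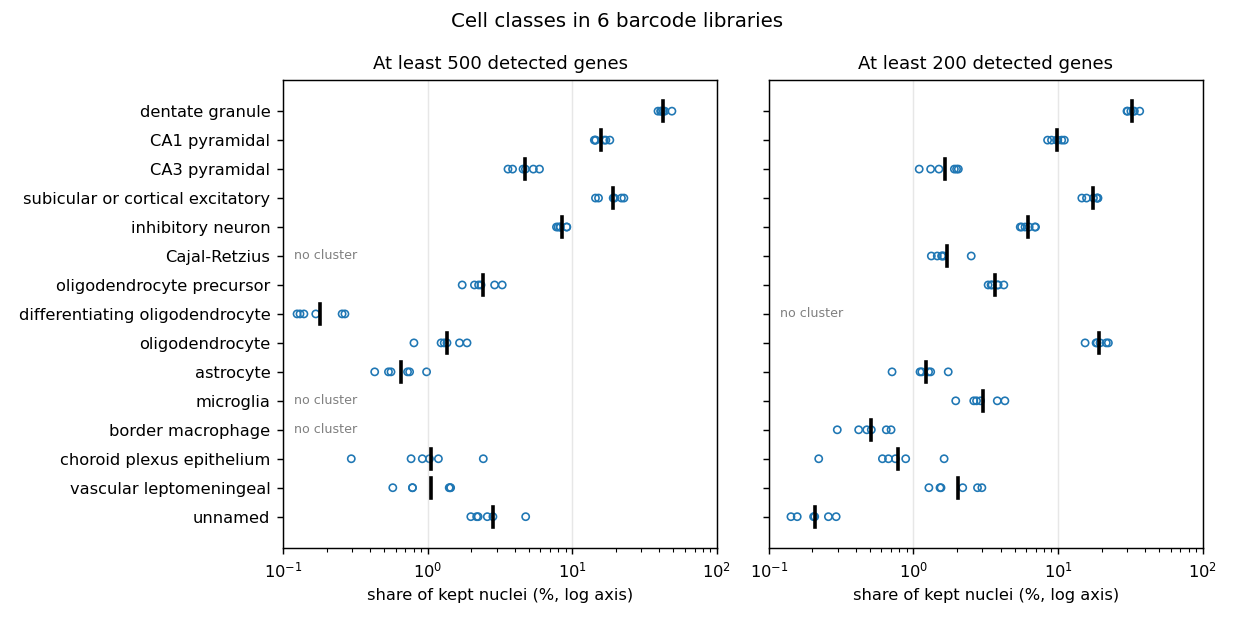
Share of kept nuclei in each cell class (percent, log axis), with 1 circle per barcode library and a black line at the pooled share, for nuclei with at least 500 detected genes (left) and at least 200 (right). Mature oligodendrocytes stand at 1.36% on the left and 19.2% on the right, and dentate granule neurons are the most frequent class in both.

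Slc12a2, the cotransporter that bumetanide blocks and that brings chloride into cells, was higher in glia than in neurons, at 174 against 38.1 CPM. The ratio was 4.57 (3.98 to 5.22) and lay between 3.66 and 5.84 in single libraries. Slc12a5, which encodes KCC2, the transporter that moves chloride out of mature neurons, was higher in neurons, at 215 against 60.9 CPM. That ratio was 3.53 (2.85 to 4.42), with 2.64 to 5.37 over libraries. Slc17a7, a gene of excitatory neurons, stood in glia at 21.6% of its excitatory level. Free neuronal RNA may therefore supply part of the glial values of Slc12a5 and of other neuronal genes, and how much was not tested. Slc12a2 is ENSMUSG00000024597 on chromosome 18 from 57878678 to 57946821, and Slc12a5 is ENSMUSG00000017740 on chromosome 2 from 164960802 to 164999731, both on the plus strand.

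The glial value of Slc12a2 came mostly from 1 class. Mature oligodendrocytes held 373 CPM (320 to 433), oligodendrocyte precursors 78.9 (58.9 to 103) and astrocytes 36.7 (15.8 to 72.2), close to the neuronal classes. Among non-glial classes outside the comparison, choroid plexus epithelium held 383 CPM (324 to 450) and vascular leptomeningeal cells 219 (175 to 270). Neuronal classes lay between 27.2 CPM in CA1 and 48.7 CPM in subicular or cortical neurons. Slc12a5 reached 238 CPM in subicular or cortical neurons, 221 in CA1, 215 in granule neurons, 194 in inhibitory neurons and 156 (143 to 170) in CA3.

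Of 23 measured genes for chloride transport and its kinases, 4 were called higher in neurons and 4 in glia. Besides Slc12a5, the neuronal ones included Car7, a neuronal carbonic anhydrase (3.88-fold, 1.88 to 9.68), and Slc4a3, a chloride-bicarbonate exchanger (2.07-fold, 1.81 to 2.37). Slc12a3, a thiazide-sensitive cotransporter, met the rule with 41 UMIs in neurons and 0 in glia, but its neuronal level of 0.918 CPM lies under the glial floor of 2.12 CPM, so the difference was not detectable at this depth. In glia, besides Slc12a2, Slc12a4, which encodes the widely expressed cotransporter KCC1, was 21.1-fold higher (12.6 to 34.8), Car2, a carbonic anhydrase, 8.87-fold (8.09 to 9.72) and Wnk1, a chloride-sensing kinase upstream of these cotransporters, 2.21-fold (2.05 to 2.38). Not called were Clcn3, Slc4a4, Slc4a10 and Stk39, whose ratios ran from 1.12 to 1.59. Counted as UMIs per nucleus, 9 genes were called higher in neurons and 3 in glia, and Wnk1 was no longer called. On that scale the Slc12a2 ratio fell to 2.85 and the Slc12a5 ratio rose to 5.66, while in CPM the Slc12a2 ratio was 7.41 with a 200-gene minimum, where glia are mostly oligodendrocytes. With every cluster named, the Slc12a5 ratio fell to 2.16, the Slc12a2 ratio was 3.48, and Wnk1, Slc4a3 and Car7 were not called. Glia then included a cluster of 348 nuclei with raised microglia and granule markers and 500.8 CPM of Slc17a7. It was left unnamed in the main set for its doublet score. After thinning to 1000 UMIs per nucleus Slc12a4 was not called.

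**Figure D2:**
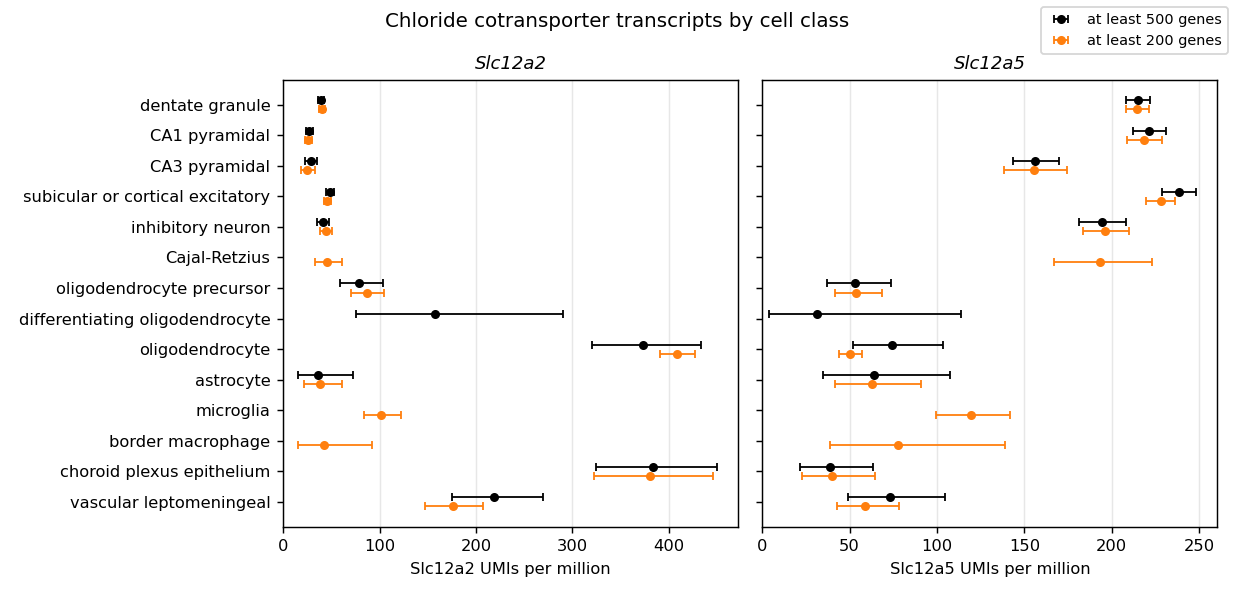
CPM of Slc12a2 (left) and Slc12a5 (right) in each cell class, with exact Poisson 95% intervals as bars, for nuclei with at least 500 genes (black) and at least 200 (orange). Slc12a2 stands at 373 in mature oligodendrocytes and 383 in choroid plexus epithelium at 500 genes, and Slc12a5 at 156 to 238 in the neuronal classes.

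Among GABA receptor genes, Gabrg1 and Gabrg3, which encode gamma subunits of the chloride-conducting GABA-A receptor, were higher in inhibitory than in excitatory neurons. Gabrg3 stood at 245 against 52.0 CPM, a 4.71-fold difference (4.37 to 5.08), and Gabrg1 at 20.7 against 3.74 CPM, a 5.53-fold difference (4.21 to 7.24). Gabra2, an alpha subunit of that receptor, was higher in excitatory neurons by 2.33-fold (2.12 to 2.58), with 274 CPM in granule neurons, 238 in CA1 and 146 in subicular or cortical neurons against 98.6 in inhibitory neurons. These were the 3 called of 14 measured. Gabbr1 and Gabbr2, the subunits of the metabotropic GABA-B receptor, were not called, with ratios of 1.03 and 1.12, nor was Gabrb1 (1.87). Gad1, which encodes a GABA-synthesising enzyme, stood in excitatory neurons at 7.65% of its inhibitory level, and Gad2, which encodes another, at 2.05%; Slc17a7 in inhibitory neurons stood at 9.93% of its excitatory level.

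Among glutamate receptor genes, Grm2, a presynaptic metabotropic glutamate receptor, was 7.74-fold higher in granule neurons than in CA1 and CA3 neurons (5.85 to 10.4), at 31.9 against 4.12 CPM. Grik3 and Grik2, subunits of kainate receptors, were 4.26-fold (3.10 to 5.99) and 2.41-fold (2.28 to 2.55) higher. Of 24 measured receptor genes 4 were called higher in granule neurons and 0 in CA1 and CA3 neurons. The abundant AMPA and NMDA receptor genes Gria2, Grin2a, Grin2b and Gria1 and the metabotropic Grm5 were not called, with ratios of 1.05 to 1.34, all higher in CA1 and CA3 neurons. As UMIs per nucleus the split was 2 against 4, as CA nuclei hold more UMIs: Grik2 was no longer called, and Gria1, Gria4, Grin3a and Grm5 were called higher in CA neurons.

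Calcium handling genes divided between the same neurons. Calb1, the calcium buffer calbindin, was 3.25-fold higher in granule neurons (2.93 to 3.60), at 111 CPM against 43.8 in CA1 and 6.98 in CA3; its granule level ran from 69.3 to 141 CPM over libraries. Pcp4, which binds calmodulin, was 3.08-fold higher in granule neurons (2.58 to 3.69). Camk4, a calmodulin-dependent kinase, was 4.35-fold (3.21 to 5.96) and Ryr3, a calcium release channel, 3.28-fold (3.11 to 3.47) higher in CA1 and CA3 neurons. That made 2 called in each direction out of 16 measured, with Atp2b1, Ppp3ca, Camk2a, Ryr2 and Camk2b not called at ratios of 1.02 to 1.74. As UMIs per nucleus the split was 1 against 6, with Pcp4 lost and Atp2b1, Calb2, Itpr1 and Cacna1a gained in CA neurons.

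Activity-regulated genes, which neurons switch on within minutes to hours of firing, were mostly lower in granule neurons than in CA1 and CA3 neurons pooled. CA1 gave 9677448 UMIs of that set and CA3 3436633, so the pooled values mostly reflect CA1. Arc, a regulator of synaptic strength, was 7.10-fold higher in CA1 and CA3 neurons (5.85 to 8.69), at 60.4 CPM in CA1 and 18.0 in CA3 against 6.94 in granule neurons. The transcription factor genes Nr4a1 (6.42-fold, 5.33 to 7.78), Nr4a3 (5.49-fold), Npas4 (5.31-fold, 4.38 to 6.47), Egr4 (3.62-fold) and Egr1 (3.37-fold, 2.88 to 3.96) went the same way, as did Homer1, a scaffold of glutamate receptors (2.81-fold, 2.63 to 2.99). Egr2 (3.09-fold), Nr4a2 (2.73-fold) and Dusp1, a phosphatase of MAP kinases (2.29-fold), were also higher there. Granule neurons instead held more Jun, an AP-1 transcription factor, by 3.38-fold (3.06 to 3.74), Bdnf, a neurotrophin, by 2.14-fold (1.97 to 2.32) and Btg2, an antiproliferative gene, by 2.08-fold (1.81 to 2.40).

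In all, 12 of 22 measured activity-regulated genes were called higher in CA1 and CA3 neurons and 3 in granule neurons. Fos, the classical immediate early gene, was not called: it was 2.61-fold higher in CA1 and CA3 neurons (1.96 to 3.50), with 144 UMIs there and 74 in granule neurons, and was higher in 5 of 6 libraries. Within the CA neurons Fos was 13.8 CPM in CA1 and 2.91 in CA3. The 2 granule clusters held 4.64 and 3.71 CPM, from 44 and 30 UMIs, so CA3 was not higher than they were and the pooled Fos difference came from CA1. With counts this low, granule and CA3 levels of Fos were not told apart. Spink8, a protease inhibitor gene of CA1 neurons, stood in granule neurons at 23.1% of its CA1 level (17.3 to 30.5), so low granule levels such as that of Arc were not told apart from free RNA. Prox1, the transcription factor of granule neurons, stood in CA1 and CA3 neurons at 4.07% of its granule level. Arc also stood at 52.5 CPM in subicular or cortical neurons and at 5.35 in inhibitory neurons. Arc is ENSMUSG00000022602, on chromosome 15 from 74669083 to 74672570 on the minus strand. As UMIs per nucleus 15 genes were called higher in CA1 and CA3 neurons and 1, Jun, in granule neurons; with 200 genes, Fos was called as well (3.30-fold) and Bdnf (1.93-fold) and Dusp1 were not. Thinning ended the calls of Fosb, Egr2 and Dusp1.

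**Figure D3:**
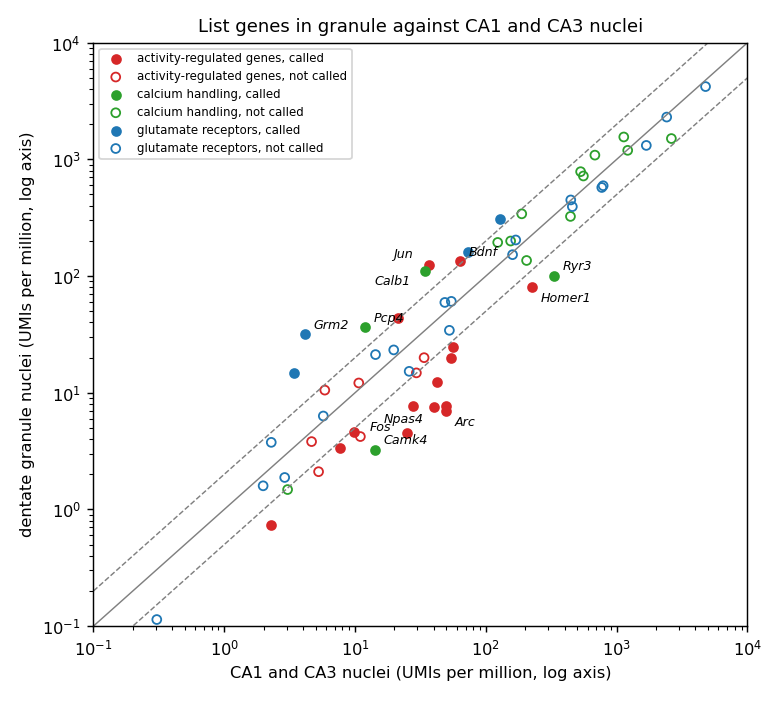
CPM in dentate granule nuclei (vertical) against CA1 and CA3 nuclei (horizontal), both on log axes, for activity-regulated (red), calcium handling (green) and glutamate receptor genes (blue); filled points were called, the solid line marks equal values and the dashed lines 2-fold differences. Arc lies at 6.94 against 49.3 and Grm2 at 31.9 against 4.12; genes with 0 in either set are not drawn.

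Of the Alzheimer-associated genes, Apoe, which encodes the lipid carrier apolipoprotein E, was 5.34-fold higher in glia than in neurons (4.56 to 6.22), at 137 against 25.7 CPM. Its level was 357 CPM in astrocytes (283 to 446), 152 in oligodendrocyte precursors and 27.6 in mature oligodendrocytes. Clu, the secreted chaperone clusterin, was 6.22-fold higher in glia (5.44 to 7.09) with 797 CPM in astrocytes, and Abca1, the transporter that loads apolipoproteins with lipid, 9.72-fold, at 101 against 10.3 CPM. Mapt, which encodes the microtubule protein tau, was 2.45-fold higher in glia (2.29 to 2.63): mature oligodendrocytes held 1292 CPM (1192 to 1399), against 233 to 289 in the neuronal classes. Neurons held more Mef2c, an activity-dependent transcription factor (3.14-fold, 2.73 to 3.63), and Ptk2b, a calcium-responsive tyrosine kinase (2.43-fold, 1.97 to 3.03).

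App, which encodes the amyloid precursor protein, was not called, at 359 CPM in neurons and 550 in glia, a ratio of 1.53 (1.42 to 1.64). As UMIs per nucleus its order turned, with 0.569 in neurons and 0.542 in glia. By class App stood at 1006 CPM in mature oligodendrocytes (917 to 1101), 202 in astrocytes and 328 to 392 in the neuronal classes. Lrp1, a receptor for apolipoprotein E, was called higher in glia (2.17-fold, 1.96 to 2.39), and Bin1, Aplp1, Aplp2 and Cd2ap were not called, at ratios of 1.33 to 1.60. Of 33 measured genes, 5 were called higher in glia and 2 in neurons. As UMIs per nucleus the split was 3 against 4, without Mapt and Lrp1. With 200 genes it was 13 against 1, App among the 13 at 2.53-fold and Mef2c and Lrp1 no longer called. At 200 genes the glia also included 1349 microglia, a class absent from the main set, and Trem2, Inpp5d and Cd33 were among the gained calls. With every cluster named it was 9 against 0, with the calls of Mef2c, Ptk2b and Lrp1 ended, and thinning ended those of Clu, Ptk2b and Lrp1. App is ENSMUSG00000022892 on chromosome 16 from 84949685 to 85173766 and Apoe is ENSMUSG00000002985 on chromosome 7 from 19696109 to 19699188, both on the minus strand. How reads from the human APP and APOE sequences of these mice were counted against the mouse genes is not given in the sources used here, so the human part of the App and Apoe counts is not known here.

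Reactive astrocyte genes were led by Gfap, the intermediate filament of astrocytes, at 252 CPM in astrocytes against 3.30 in all other classes together (76.3-fold, 55.0 to 104). C4b, a complement component, was 34.7-fold higher (25.3 to 46.8), Id3, an inhibitor of helix-loop-helix transcription factors, 26.2-fold (19.3 to 34.9) and Cst3, the protease inhibitor cystatin C, 17.9-fold (16.5 to 19.4). Those 4 of 22 measured genes were called higher in astrocytes. The calls compare classes of the same mice, with no mice of another genotype, so they do not show a reactive state. The other classes were mostly neurons, with 44649449 UMIs in neuronal classes and 1411990 in all glial classes together. Cp, S1pr3, Hspb1 and Timp1 met the rule in the other direction with 0 UMIs in astrocytes, yet their levels elsewhere, at most 3.35 CPM, lie under the astrocyte floor of 13.7 CPM, so those differences were not detectable at this depth. Cd9 and Stat3 held 18 and 12 UMIs in astrocytes, too few for a call, and Ctsb was not called at a ratio of 1.23. The astrocyte class held 204 nuclei with a median of 971.5 UMIs, so thinning to 1000 UMIs per nucleus left out a large part of it. Gfap, C4b and Id3 were then no longer called, and whether the loss of nuclei and UMIs alone ended these calls was not tested.

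Mature oligodendrocytes held more C4b than the other classes together, by 29.4-fold (22.8 to 37.7), at 178 against 6.06 CPM and with 43.3 to 386 CPM in single libraries. Here too the other classes were mostly neurons, and C4b was also called higher in astrocytes, so it is not particular to oligodendrocytes. Il33, an alarmin cytokine, was 21.8-fold (16.1 to 29.0), Apod, the lipid-binding apolipoprotein D, 18.3-fold (16.4 to 20.2), Ptgds, which makes prostaglandin D2, 6.11-fold (5.64 to 6.61) and Cd63, a membrane protein of late endosomes, 3.41-fold (2.36 to 4.77) higher. That made 5 of 12 measured disease-associated oligodendrocyte genes higher in this class and 0 lower. With no mice of another genotype, these calls do not show a disease-associated state. After thinning, C4b, Il33 and Cd63 were not called. With 200 genes, where the class held 8613 nuclei, 9 of the 12 were called, adding Serpina3n, Klk6, B2m and S100a6. After thinning Serpina3n was called lower with 0 UMIs in the class, but a level like that of the other classes was not detectable there.

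No microglia class was named at 500 genes, so disease-associated microglia genes are given here for the 1349 microglia of the 200-gene setting. In the main set 317 of these nuclei lay in a cluster with raised microglia and granule markers and 63 in one with raised microglia and oligodendrocyte markers, both left unnamed for their doublet scores. Unnamed clusters gave 55.1% of the UMIs of this class, so its values mix microglia with RNA of other cells. Trem2, a lipid-sensing receptor of microglia, was 42.5-fold higher there than in the other classes (35.3 to 51.2), at 199 against 4.67 CPM, and its adaptor Tyrobp 22.9-fold (17.4 to 29.8). The lysosomal genes Cd68 (14.3-fold), Ctsd (11.8-fold) and Ctsb (3.04-fold), the MHC class I subunit gene B2m (7.09-fold) and the tetraspanin genes Cd9 (3.45-fold) and Cd63 (2.33-fold) were also higher. Of 22 measured genes 8 were called higher in microglia and 0 lower, and Apoe was not called, at 36.1 against 33.3 CPM. How reads of the human APOE4 allele of these mice were counted is not known here, so the Apoe values do not give the level of that allele in microglia. Fth1 and Timp2 were not called either, with ratios of 1.34 and 1.87. Slc17a7 stood at 49.9% of its excitatory level in this class (44.9 to 55.3), so the uncalled genes are not shown to be equal in microglia and other cells. Nor do the called genes show a disease-associated state, as no mice of another genotype were included.

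Among clock genes, Rorb, a nuclear receptor, was 11.7-fold higher in glia than in neurons (9.88 to 13.7), with 669 CPM in astrocytes and 83.4 in oligodendrocyte precursors, and its relative Rora was 2.32-fold higher (1.79 to 2.95). Npas2, a partner of the core clock factor Arntl, was higher in neurons by 2.37-fold (1.19 to 5.51), resting on 8 UMIs in glia. Of 18 measured genes, 1 was called higher in neurons and 2 in glia, while Per3, Tef, Clock, Cry2 and Bhlhe41 were not called, at ratios of 1.05 to 1.35. As UMIs per nucleus the split was 4 against 1, with Per1, Cry2 and Arntl added in neurons and Rora lost. Rora was also lost with 200 genes, after thinning and with every cluster named; after thinning Npas2 was lost as well and Per2 gained.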

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

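Of the tests weighed here, all but the comparison of Lct and Trhr were chosen only after the result they measure had been seen.

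In library 4, 73.8% of the dentate granule nuclei fell in the second granule cluster and 26.2% in the first, far from the other libraries, where the second cluster held 40.2, 42.9, 43.7, 46.2 and 48.0% in libraries 1, 2, 3, 5 and 6. Technical accounts met values against them: with no doublets removed the matching share was 80.2%, against 53.0 to 58.1% elsewhere; the median granule nucleus of library 4 held 1311 UMIs, within the 1234 to 1330 of the others; and a shift of the whole library meets the finding that 2 of 3130 CA1 genes in library 4 lay beyond all other libraries by 0.5 on the log2 scale, against 68 of 5490 genes in granule nuclei. A different mix of dorsal and ventral tissue may contribute and cannot be told apart, since Trhr, a gene of ventral granule cells, was lowest in library 4 at 3.54 CPM (7.88 to 14.1 elsewhere) while Lct, a gene of dorsal ones, lay within the others at 24.2 CPM (17.5 to 24.7). No biological explanation was tested, because the treatment of library 4 is not known.

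The share of unnamed nuclei was 4.76% in library 2 and 1.99 to 2.82% in the others, the other value that stood far from the rest. In library 2, 178 of the unnamed nuclei lay in 1 cluster with raised Cajal-Retzius and inhibitory markers. That cluster held 34 to 77 nuclei in each other library. In all, 30 values were tested over the 6 libraries and 3 stood apart, of which 2 are the same granule split; chance alone marks about 1 in 20 such values.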

How the results depend on the processing

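The alternatives that name every cluster and that use the doublet threshold of library 4 itself were chosen after the data had been seen; the others were planned. No paired analysis was possible because the libraries carry no sample label, and for the same reason the treatment fits with edgeR or DESeq2, with and without a filter on low counts, a replicate block or samples left out were not run. Of 211 planned and 24 added recomputed values, 25 and 4 moved beyond their limit. Most of these values are counts of called genes in either direction, which cannot reverse; as UMIs per nucleus the split of glutamate receptor genes went from 4 in granule and 0 in CA neurons to 2 and 4, and that of Alzheimer-associated genes from 5 in glia and 2 in neurons to 3 and 4. The ratios of Slc12a2 and Slc12a5 kept their direction in all alternatives that gave a value.

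The share of neuronal nuclei, 90.5% in the main set, was 69.3% with 200 genes, 93.0% with 1000 genes, 90.8% with a mitochondrial limit of 1%, 86.0% without doublet removal, 94.3% after thinning, 89.7% with each library's own doublet threshold and 91.8% with every cluster named; leaving out libraries gave 90.1 to 90.9%. The Slc12a2 ratio of glia over neurons was 7.41 with 200 genes, 2.85 as UMIs per nucleus and 3.48 with every cluster named. The Slc12a5 ratio of neurons over glia was 2.71 after thinning, 5.66 as UMIs per nucleus and 2.16 with every cluster named. At 1.5-fold, 8 GABA receptor, 9 calcium handling, 15 Alzheimer-associated and 5 clock genes were called. At 3-fold, 2 glutamate receptor, 8 activity-regulated, 4 Alzheimer-associated and 1 clock gene remained past the rule. As UMIs per nucleus, 7 calcium handling and 5 clock genes were called. With 200 genes, 14 Alzheimer-associated and 9 oligodendrocyte genes were called; after thinning, 4 reactive astrocyte and 3 oligodendrocyte genes. The chloride list stayed within 1.5 times its main count of 8 in all alternatives that gave a value, but the genes called changed. As UMIs per nucleus 12 were called, of which 7 were main calls. With every cluster named 6 were called, of which 5 were main calls. No gene was called in opposite directions between the main set and the settings with 200 genes, thinning, UMIs per nucleus or every cluster named. Between settings 2 were: Cd33 was called higher in glia and Serpina3n in mature oligodendrocytes with 200 genes, and both the other way after thinning, each with 0 UMIs in the lower set. Levels as low as those of Cd33 in neurons and of Serpina3n in the other classes were not detectable there after thinning. These calls therefore do not show a reversal. The cause of the other changes was not tested, except that looser or stricter folds pass more or fewer genes by construction. With 1000 genes no glial class was named, so comparisons with glia had no value. Microglia had no main value; with every cluster named, 6 of 22 genes were called higher.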

Other observations

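The comparisons of granule clusters, of App and of single genes across libraries were chosen after the data had been seen, as were the tests reported here, except that the bound for the scaling of libraries was written before its result.

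The 2 granule clusters also differed in list genes that took no part in the clustering. They differed in depth as well, with a median of 1369 UMIs in the first and 1184.5 in the second. Library 4 gave 600 of 6723 nuclei of the first and 1687 of 6532 of the second. The pooled folds therefore also hold differences between libraries, and how much was not tested. The second cluster held more Nptx2, a synaptic pentraxin induced by activity (5.96-fold, 3.09 to 12.6), Gpnmb, a membrane glycoprotein (5.85-fold, 3.60 to 9.99), Penk, which encodes enkephalins (4.24-fold, 2.97 to 6.18), and Bdnf, at 186 against 91.0 CPM (2.04-fold, 1.88 to 2.22). Wnk4, a kinase that acts on chloride cotransporters (2.48-fold), and Lpl, lipoprotein lipase (2.20-fold), completed its 6 of 196 list genes. The first cluster held more of 5: Slc12a4 and Mme, which encodes the amyloid-degrading enzyme neprilysin (both 3.76-fold), Slc4a4, a sodium-bicarbonate cotransporter (2.13-fold, 2.01 to 2.27), Abca7 (2.12-fold) and Plcg2 (2.01-fold). Each of these was higher in the same cluster in all 6 libraries. For Slc12a4, with 22 against 5 UMIs (1.39 to 12.7), and Mme, with 44 against 10 (1.86 to 8.38), this rests on few UMIs per library. Library 4, which held most of its granule nuclei in the second cluster, had 179 CPM of Bdnf and 20.9 of Penk in granule nuclei, against 102 to 145 and 5.35 to 11.3 elsewhere, and 69.3 CPM of Calb1 against 94.2 to 141. These values are not independent of the difference between the clusters.

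App in granule nuclei was 446, 459, 194, 429, 363 and 185 CPM in libraries 1 to 6, so that libraries 3 and 6 lay well under the rest, as they were the lowest in each neuronal class. In glia together libraries 3 and 6 were also the lowest, at 388 and 363 CPM against 580 to 721 in the other libraries. Scaling or depth is an unlikely sole source, since only 20 of 3447 genes above 50 CPM, or 0.580%, had as large a ratio of highest to lowest library as App (2.48; the median gene had 1.31). Free RNA stays open as a part of it: the gap between highest and lowest library was 135 CPM in inhibitory nuclei (74.9 to 195) and 195 in CA1 (152 to 237), smaller than the 273 of granule nuclei (245 to 302), but the 212 of CA3 (140 to 285) and the 228 of subicular or cortical nuclei (187 to 269) have intervals that overlap it. A difference in transgene expression, in treatment or in genotype stays open and was not tested, and the libraries were not grouped by it.

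Other genes also varied between libraries in granule nuclei. Ap3m1, which encodes a subunit of the AP-3 vesicle adaptor, was 329 CPM in library 1 and 405 in library 5 and 49.3 to 54.5 in the other libraries; in CA1 nuclei the values were 275 and 276 against 63.1 to 91.7. Col6a1, a collagen VI chain, was 282 CPM in granule nuclei of library 4 and 17.8 to 73.4 elsewhere, while in its CA1 nuclei it was 77.9 within a range of 42.7 to 89.4. Apoe in neurons was 48.9, 14.7, 29.2, 13.9, 34.3 and 12.5 CPM in libraries 1 to 6, and in astrocytes 579, 221, 396, 334, 443 and 163 CPM, from 78 UMIs in all. In library 5, 20 genes of CA1 nuclei, 31 of subicular or cortical nuclei and 13 of inhibitory nuclei lay beyond all other libraries by 0.5 on the log2 scale, the highest count among the 6 libraries in each of these classes. Ttr, the choroid plexus transcript for transthyretin, was also highest there in neurons, at 333 CPM against 123 to 259, in the library with the highest choroid plexus share.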
